A study of Picea glauca with 115 samples.

How the data were processed

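Genomic DNA from needles of white spruce (Picea glauca) was compared on a 2-colour comparative genomic hybridization (CGH) array, in which DNA of 2 trees is labelled with 2 dyes and hybridized to the same probes, so that the ratio of the dyes at a gene's probes follows the ratio of that gene's copies. Per the labels, 114 descendants of 1 controlled cross were each hybridized with their mother, and 1 further array held the other parent against the mother. Per the labels, Cy5 marked the sample and Cy3 the mother on each array.

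The deposited files give a trimmed mean intensity of spot and local background per probe and dye, and the net intensity, which equals spot minus background within 1.0e-06. Per the file headers, they also give a log2 ratio of Cy5 over Cy3 per probe, and the values show that it was normalized within each array by a shift that follows intensity. The authors' log2 columns go on to residuals after linear regression on probe base counts and on the GC content of the gene, which the deposited files list as a fraction. The authors' call per probe is a score of 1, 0 or -1, set where the corrected ratio passed a limit that differed between files. The submitters' processing notes name R 3.1.3. The image software and probe filters are not given in the sources used here. The series value table holds the same log2 ratios as the array files within 5.0e-08. Its column medians ran from -0.059 to 0.044, its direction is Cy5 over Cy3, and the authors' reason for its scale stays unknown. In 18 of the 115 files the data columns were shifted against the header, in 16 by a missing cell and in 2 by an extra one, and columns were set right from the values before use. The corrected ratios, the GC fraction and the authors' calls entered no test.

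The values used here start from the net intensities. For each of 61896 probes with a gene name, log2 of the net intensities was taken where both were positive, the log2 ratio was centred on each array's median, and the mean over a gene's probes was formed for genes with at least 3 usable probes. This gave 5629 genes with 4 to 60 probes each (median 9). No loess or quantile normalization was applied, since many genes may truly shift one way. Gene identifiers are those of the files' gene column. The files do not pair them with descriptions, so no function is given for any gene.

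The dye orientation given by the labels was checked against the intensities. Each array was first assigned to the dye whose gene profile correlated more with the Cy3 profile of the other parent's array. The Cy3 profile of each array was then correlated with the median Cy3 profile of the arrays assigned to Cy3, and its Cy5 profile with the median Cy5 profile of those assigned to Cy5; these medians are called the shared profile below. An array was left without an assigned orientation where the higher correlation was under 0.9 and the difference between dyes under 0.05, a rule set after the values had been seen. Arrays whose Cy5 carried the shared profile had their ratio's sign turned, so that the mother was the denominator throughout. The 5 unassigned arrays kept the labelled direction. Array noise was taken as 1.4826 times the median absolute deviation of gene log2 ratios from the descendants' medians. The 11 noisiest arrays, which one of the other settings leaves out, were ranked on 1.4826 times the median absolute probe log2 ratio. That measure does not subtract the descendants' medians. Ranked by gene noise, trees 163 (0.617) and 80 (0.531) would take the places of trees 746 (0.524) and 690 (0.501) among the 11. A second look was restricted to the 65 arrays with a noise under 0.25 and an assigned orientation. That limit was chosen after gene counts at limits of 0.25, 0.3, 0.35 and 0.4 had been seen, and the counts at each are given with the alternatives.

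A gene was called segregating when a mixture of 2 normal classes with equal variance described the 114 ratios better than 1 class. The likelihood ratio p came from 100000 simulated normal samples of the same size, so that 1.0e-05 is the smallest p they can give. A call needed a Benjamini-Hochberg adjusted p under 0.05, class means at least 0.4 log2 and 3 within-class SDs apart, and at least 6 trees in the smaller class. Class sizes were set against 1:1 and 3:1 by exact two-sided binomial tests. Recombination fractions and LOD scores (the log10 odds of linkage) were computed for each pair of segregating genes, with groups formed by single linkage at a LOD of at least 5 and a chance level from 100 permutations of trees within each gene. The other parent was set against the descendants with limma (lmFit and eBayes), with the lone array assumed to vary like the descendants. Its ratio to the mother was read by a rule of size, 0.5 log2, since 1 array has no replicate check. A rare deviation was a gene and direction for which 1 to 3 trees, and not the other parent, passed both of 2 limits: at least 0.5 log2 from the descendants' median, and at least 3 in 4 of the gene's probes at least 0.3 log2 off on the same side. More trees can pass the first limit alone, so such a deviation need not be rare by size. Its gains and losses were compared by an exact two-sided binomial test over genes, which are not independent replicates.

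These tests, their thresholds, most of the other settings and the rule for named genes were fixed before the data were examined. The turning of arrays, the noise-limited arrays, the background bands, the orientation term and the other settings listed as such in the closing part were added after. The rule for named genes took the 10 genes with the largest class distance whose lower class lay below the mother, the 10 whose upper class lay above it, the 5 with the smallest transmission p, up to 8 genes up and 8 down in the other parent, the 5 largest rare gains and 5 largest rare losses, and the 5 genes with most partners in the largest group of linked genes. Because the identifiers carry no description, at most 2 genes per direction are written out in each comparison and the other genes of the rule are summarised. For segregating genes these are the largest distance of each 10 and the gene with the most even classes of each 10, a choice made after the values were seen.

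On simulated data with 200 of 5629 genes segregating at a class distance of 1 log2, the procedure recovered 100% with equal noise on all 114 arrays and made 3 false calls. With each array's own noise it recovered 95% and made 588 false calls. In the 65 quietest arrays with their own noise it recovered 100% with 9 false calls, and at a distance of 0.6 log2 it recovered 83.5%. At 0.6 log2 in 114 arrays with their own noise, recovery was 6%. Planted genes put each tree in either class with equal chance. Recovery of genes with a small class was therefore not simulated. For the limma comparison, 98% of 200 genes planted at 2 log2 were recovered with 4 false calls. Linked pairs at 5% recombination in 65 trees were recovered in 100% of 100 planted pairs and rare deviations of 1 log2 in 100% of 100, with 0 false calls in both. The rare deviations were simulated in 60 trees with the same probe noise of 0.3 on each array. On the real arrays the scaled median absolute probe log2 ratio reached 1.73 (tree 775). The 0 false calls for rare deviations therefore do not carry over to the 114 arrays.

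Each array is a separate tree, and no array was a copy of another, since the highest correlation over genes between 2 descendants was 0.907. Slide and scan are not given in the sources used here. Slot on the slide and 5 bands of median Cy5 background were used as technical groups instead. Enrichment of gene lists was not run, since no table pairs the genes with descriptions. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.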

Results

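Copy number differences between genes of white spruce trees were measured in a family of full sibs, to follow which gene copies pass from parents to offspring. The arrays covered 114 descendants of a controlled cross and the other parent, each against the mother, with 1 array per tree. Usable probes per array ranged from 38863 to 61881 of 61896 (median 61627), and they measured 5629 genes, with 0.273% of gene and tree values missing. Median net intensity per array ran from 114 to 1401 in Cy3 and from 29.9 to 1118 in Cy5. Signal over background differed widely between arrays. Median Cy5 net intensity was 13.5 times the background on the 42 arrays with the lowest Cy5 background and 0.209 times the background on 32 others. Array noise in gene log2 ratios had a median of 0.216 over the descendants (range 0.0966 to 0.822) and was 0.268 on the other parent's array.

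The gene profile shared between arrays, which should be that of the mother, was found in Cy3 for 67 descendants and the other parent, as labelled. In 42 descendants it was found in Cy5, assigned by the higher correlation of Cy5 with the Cy3 profile of the other parent's array. Their Cy5 correlated over genes at a median of 0.993 with the median Cy5 profile of these same arrays, a value high by construction. Their Cy3 correlated at a median of 0.886 with the median Cy3 profile of the other arrays. Log2 ratios of Cy5 over Cy3 on these 42 arrays correlated negatively over probes with those of the other arrays (median r = -0.33, and r under -0.3 in 1681 of 2856 pairs across the 2 sets), although the labels give all of them the same dyes. The direction of the ratios is therefore not settled by the labels. A likely direction, with the mother as denominator, rests on which dye varies between arrays. Over 59 genes with well separated classes, the SD between the 42 arrays was 0.731 in Cy3 and 0.186 in Cy5, and on the 67 other descendants' arrays it was 0.265 in Cy3 and 0.754 in Cy5. The signs of the 42 arrays were turned accordingly. If the opposite sign were the true one, gains below would be losses and losses gains, so that upper and lower classes exchange places in each comparison. In 5 descendants (trees 396, 403, 420, 463 and 518) neither dye followed the shared profile (r at most 0.889). Their files are all among the 16 with a missing cell, and their median Cy5 backgrounds all lie in the band from 149 to 341. The other 11 arrays of that band were assigned to Cy3, such as tree 33 (r of 0.961 in Cy3). Whether the file batch plays a part was not tested. Cy3 profiles of trees 396, 463 and 518 correlated with each other at 0.986 or more, those of trees 403 and 420 at 0.992, and across these sets at 0.922 or less.

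**Figure D1:**
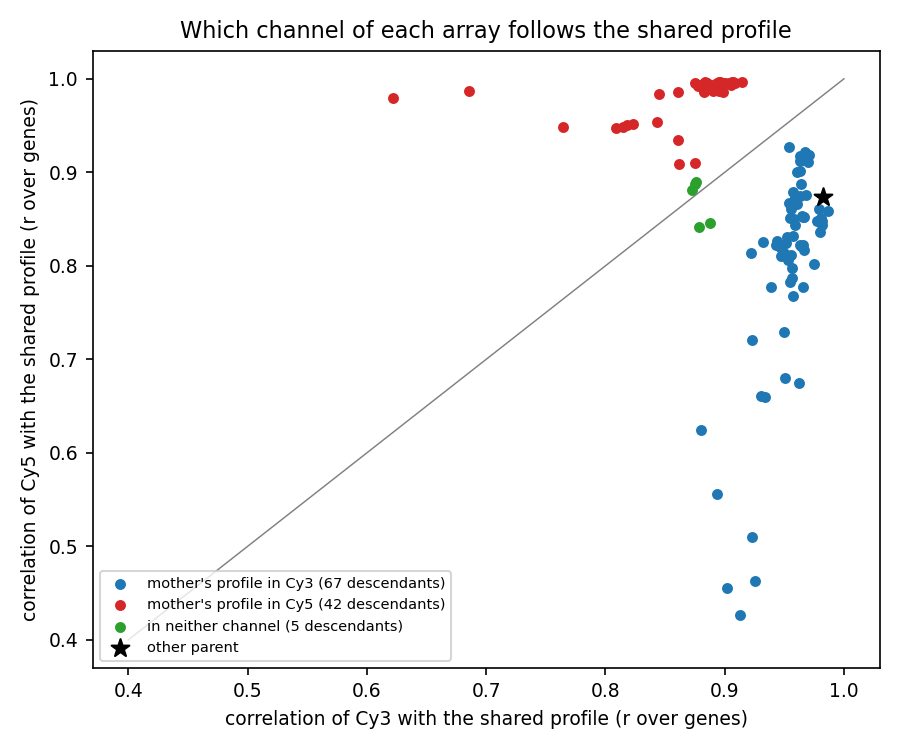
Correlation over genes of each array's Cy3 profile (x axis) and Cy5 profile (y axis) with the shared profile of the same dye, 1 point per array and the other parent as a star. The 42 red arrays lie above the line of equal correlation, the 67 blue ones below it, and the 5 green ones near it with r at most 0.889.

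Many genes fell into 2 classes of trees, with class distances from 0.41 to 4.03 log2. The largest belonged to GQ03610_N24, which had a lower class of 37 trees (mean 0.0034 log2) and an upper class of 77 (4.03 log2, within-class SD 0.65, n = 114), and whose value in the other parent was 3.32 log2. The lower class of GQ03610_N24 includes the 5 arrays in which neither dye followed the shared profile, at -4.58 to 1.35 log2, and its other 32 trees lay at -0.25 to 1.89 log2 (mean 0.17 log2). GQ04006_O12 had nearly even classes, 63 trees at 0.016 log2 and 51 at 2.15 log2 (SD 0.42), while the other parent, at 0.061 log2, lay with the lower class. WS00838_P15 had a lower class of 30 trees (mean -1.69 log2) and an upper class of 84 (mean 0.48 log2, SD 0.50). Some trees of that upper class lay below the mother, such as tree 34 (-0.027 log2). GQ03507_H08 was low in 73 trees (-1.24 log2) and high in 41 (0.47 log2, SD 0.35), with the other parent at 0.36 log2. The 5 arrays were in the lower class of GQ04006_O12 and in the upper class of WS00838_P15 and GQ03507_H08.

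By the mixture test, 1682 of 5629 genes segregated, with an adjusted p of 2.6e-05 for each of these 4 genes. The class farther from the mother was the lower one in 1284 genes and the upper one in 398 (with the sign turned, 398 and 1284). Of the 10 genes with the largest distances among those with a lower class below the mother, which spanned 1.64 to 2.17 log2, 7 were also called in the 65 quietest arrays, but only 4 with at least 95% of the trees in the same class. Of the 10 with an upper class above it (2.13 to 4.03 log2), 8 were called with such classes, and these 8 include GQ03610_N24 and 6 genes that shared its classes. Most of the 1682 genes had a small minor class. It held 6 to 10 trees in 1341 genes, 11 to 19 in 292 and 20 or more in 49. In the genes with 6 to 10 such trees, a median of 50% of them came from the 11 noisiest arrays, which hold 9.65% of the trees. In those with 20 or more the median was 9.80%.

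In the 65 quietest arrays 288 genes segregated. Of them 74 were among the 1682, fewer than the 86.1 that chance gives, and 48 of the 74 had at least 95% of the trees in the same class in both. Their minor class was larger, with 20 to 32 trees in 156 genes, 10 to 19 in 71 and 6 to 9 in 61. GQ04006_O12 split 33 to 32 there (-0.11 and 2.10 log2, SD 0.36), GQ03507_H08 40 to 25 (-1.06 and 0.53 log2, SD 0.17), WS00838_P15 14 to 51 (-1.55 and 0.52 log2, SD 0.38), and GQ03610_N24 16 to 49 (0.07 and 4.15 log2, SD 0.36). The farther class was the lower one in 145 of the 288 genes and the upper one in 143 (143 and 145 with the sign turned). Among genes with the lower class farther from the mother, the other parent lay nearer to that class in 52 of 145. Among genes with the upper class farther, it did so in 66 of 143. Class and dye orientation went together in 32 of the 288 genes by Fisher's exact test (two-sided, adjusted over the 288), and 195 genes segregated in the 40 quietest arrays with the mother in Cy5 alone, of which 157 were among the 288. Counts depended on array noise, and simulated arrays with these noise levels gave 588 false calls among 114 trees but 9 among the 65 (1 log2 planted). The simulated noise was independent between genes, with 1 SD per array for all of them. The 9 is therefore no upper bound on false calls among the 288. The array limit was chosen after seeing the data, and limits of 0.3, 0.35 and 0.4 gave 597, 809 and 1287 genes, of which 221, 200 and 168 were among the 288.

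**Figure D2:**
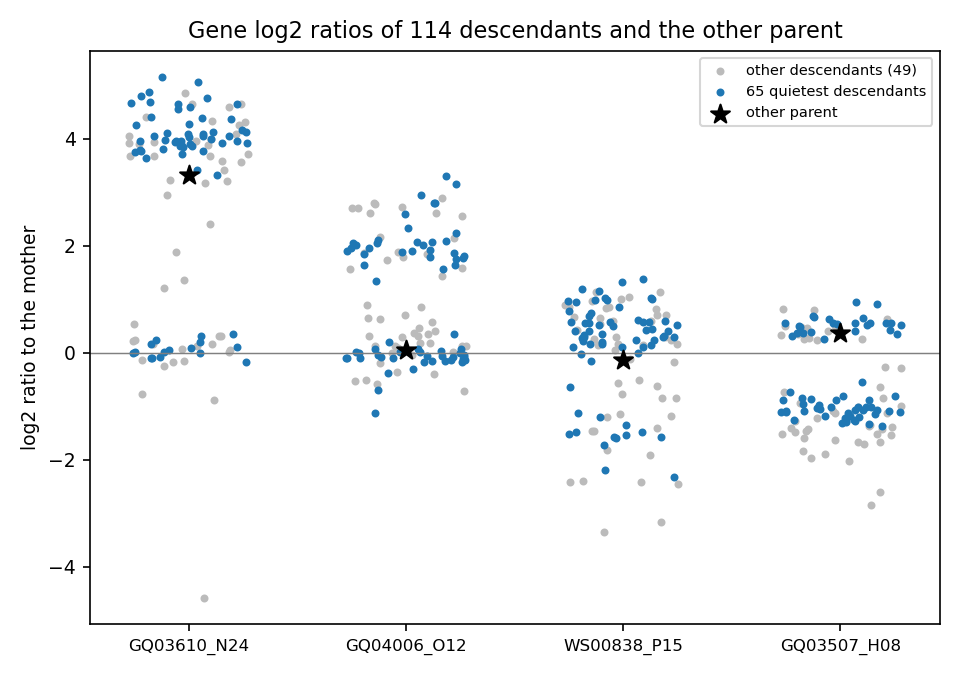
Gene log2 ratio to the mother (y axis) of 4 genes in 114 descendants, with the 65 quietest arrays in blue, the 49 others in grey and the other parent as a star. Among the blue points GQ03610_N24 forms 2 clouds of trees, near 0.07 and 4.15 log2. WS00838_P15 has trees between its class means, such as tree 18 (-0.636 log2) and tree 34 (-0.027 log2). Points are spread sideways only for legibility.

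**Figure D3:**
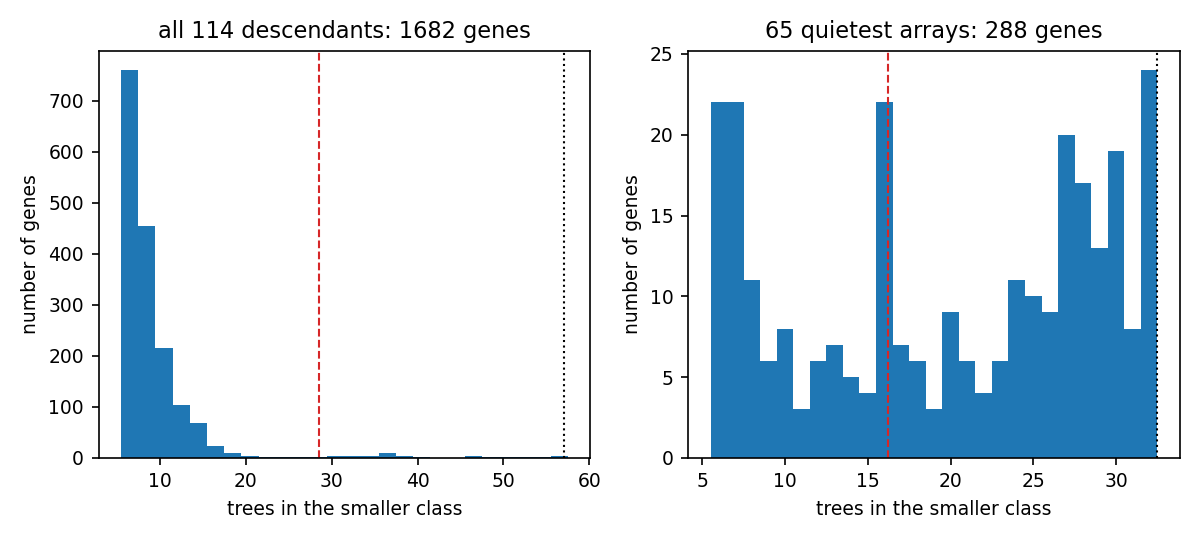
Number of genes (y axis) by the number of trees in the smaller class (x axis), for the 1682 genes called in 114 descendants (left, bars 2 trees wide) and the 288 called in the 65 quietest arrays (right, bars 1 tree wide). The dotted and dashed lines mark class sizes of 1:1 and 3:1; most genes at left lie at 6 to 10 trees, and 156 at right lie at 20 to 32.

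A gene copy carried on 1 of a parent's chromosomes should reach about as many trees as it misses. Of the 4 genes written out above, GQ04006_O12 came closest to 1:1 (51 of 114 trees in the upper class, exact binomial p = 0.303, adjusted p = 0.304). GQ03610_N24 departed from 1:1 (77 of 114 trees, adjusted p = 0.000229) and not detectably from 3:1 (adjusted p = 0.0837). WS00838_P15, at 84 of 114, departed from 1:1 (adjusted p = 4.4e-07) and not detectably from 3:1 (adjusted p = 0.747), and GQ03507_H08, at 41 of 114, departed from both (adjusted p = 0.00353 and 0.00944). The strongest departures were ties with 6 of 114 trees in the smaller class, as in GQ0015_B23 (adjusted p = 1.3e-24). A class of 6 is the smallest that a call allows, and 4 of the 6 trees of GQ0015_B23 were among the 11 noisiest arrays, so its call ends by construction without them.

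Of all 1682 genes, 1670 departed from 1:1, and 32 of these did not depart from 3:1. In the 65 quietest arrays 157 of 288 genes departed from 1:1 and 131 did not, while 55 of the 157 departed from 3:1 as well. GQ04006_O12 (adjusted p = 1) and GQ03507_H08 (adjusted p = 0.132) were among the 131. The 5 arrays without an assigned orientation count in these tests. Without them GQ03610_N24 had 77 trees against 32 (unadjusted exact binomial p = 1.9e-05), GQ04006_O12 51 against 58 (p = 0.566), WS00838_P15 79 against 30 (p = 3.0e-06) and GQ03507_H08 36 against 73 (p = 0.000505). A turned sign exchanges the classes and leaves these counts as they are.

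Genes close together on a chromosome are inherited together. No gene positions are given, so linked here means only a LOD of at least 5. In the 65 quietest arrays, the 131 genes with classes not departing from 1:1 formed 120 linked pairs, against at most 1 in 100 permutations, and 92 of the genes fell into 30 groups. The largest group held 10 genes with a median recombination of 7.69% between pairs, among them GQ03112_F15 (-0.94 log2 in 27 trees and -0.07 log2 in 38, SD 0.14) and WS00110_K19 (-0.45 log2 in 30 trees and 0.32 log2 in 35, SD 0.23). The other groups held 6, 5, 4, 3 or 2 genes. Across all 114 trees as planned, 1682 genes gave 1348238 linked pairs, but permuted trees gave a median of 1344521, because a LOD that assumes even classes links any pair of genes with few trees in the smaller class. The 5 genes with most partners there had 7 to 14 trees in the smaller class. Without genes departing from 1:1, 12 genes and 1 linked pair were left in 114 trees.

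The other parent differed from the mother by at least 0.5 log2 in 680 of 5629 genes, 301 above and 379 below (379 above and 301 below with the sign turned). GQ03610_N24 was 3.32 log2 above the mother, GQ03109_C06 1.78 log2 above it, and WS00810_N04 lay at -2.33 log2. This is 1 array, so none of these differences has a replicate check. Counts at thresholds of 0.3 and 1 log2 were 1796 and 90. With normexp background correction 526 genes were above and 387 below, so that the share above moved from 44.3% to 57.6% (from 55.7% to 42.4% with the sign turned). Dye bias per gene was taken as the unturned ratio averaged within each of the 2 orientations and then over both. No gene had a bias over 0.3 log2 (largest 0.27 log2). Turned values differ between the orientations by 2 times that bias. Dye and batch cannot be told apart in it, since all 42 turned arrays lie in the lowest Cy5 background band.

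For 2 genes limma called a difference between the other parent and its offspring, on the assumption that the lone array varies like the descendants' arrays. GQ03109_C06 was 1.82 log2 higher in the other parent than the mean of the descendants (SE 0.37, limma adjusted p = 0.00649), above all 114 of them. WS00810_N04 was lower by a difference of -2.26 log2 (SE 0.40, limma adjusted p = 0.000654), below each descendant with a value. With the sign turned the 2 genes exchange directions. Neither gene segregated, and in the 65 quietest arrays the descendants' medians were -0.04 log2 (SD 0.14) and 0.04 log2 (SD 0.23). Within the other parent's own Cy5 background band the differences were 1.69 log2 (limma adjusted p = 0.0230) and -2.15 log2 (limma adjusted p = 0.00948). An unadjusted limma p under 0.05 was reached by fewer genes than chance alone would give, so these genes are no evidence of further differences. Both calls ended with normexp (0.88 and -0.999 log2) and with the median over a gene's probes (0.43 and -1.22 log2). The call of WS00810_N04 also ended with loess (-1.42 log2), with the deposited log2 ratios (-1.42 log2) and without the dimmest probes (-0.50 log2). Quieter sets of descendants gave more genes, 17 without the 11 noisiest arrays and 349 against the 65 quietest, arrays less noisy than the other parent's own.

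**Figure D4:**
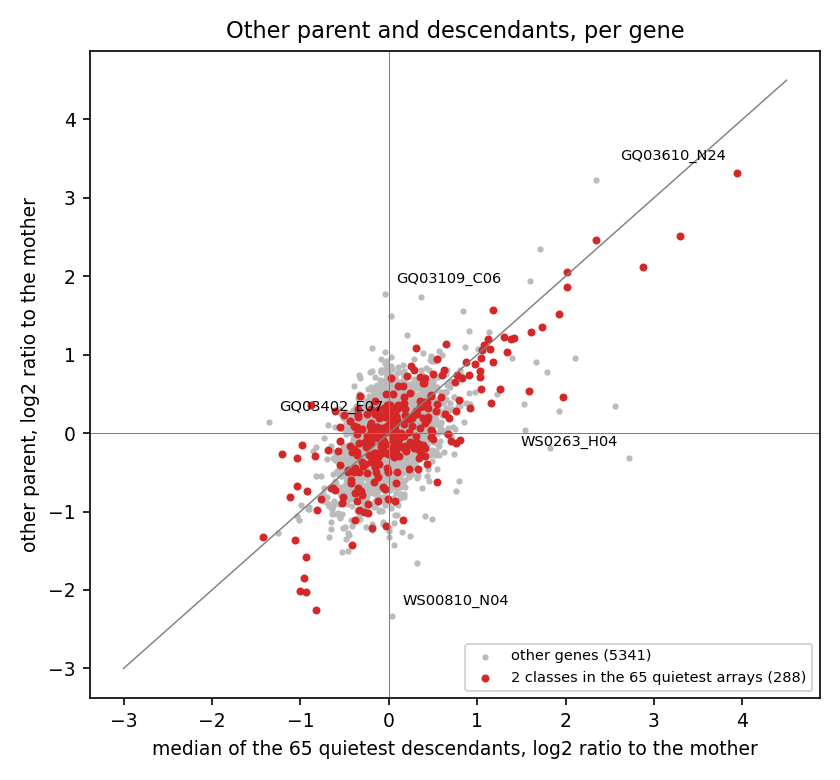
Other parent's log2 ratio to the mother (y axis) against the median of the 65 quietest descendants (x axis), 1 point per gene, with the 288 genes that segregate in those arrays in red and 5 genes written out. GQ03109_C06 and WS00810_N04 lie at 1.78 and -2.33 log2 in the other parent with descendants' medians near 0; the diagonal marks equal values.

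Single descendants differed from the mother by at least 0.5 log2 in a median of 704 genes (range 207 to 2969 over 114 trees), with medians of 312 genes above and 334 below (334 above and 312 below with the sign turned). In the 65 quietest arrays the median was 449 genes (207 to 972). Measured from the descendants' median in place of the mother, it was 357.5 genes. Over all trees 42.3% of deviating genes were above the mother, and 58.6% with normexp (57.7% and 41.4% with the sign turned). Array noise adds to this number by construction.

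For some genes 1 to 3 trees, and not the other parent, passed the limits on both size and share of probes on one side of the family's median. The largest gain was GQ03112_E06, 2.94 log2 in trees 403 and 420, and the largest loss GQ03224_L02, -4.31 log2 in trees 396, 463 and 518. Measured the same way, the other parent lay at -1.99 log2 for GQ03112_E06 and at -1.09 log2 for GQ03224_L02, where too few of its probes passed. These are the same 2 sets of trees whose Cy3 profiles stood apart from the shared one, so neither value is shown to be a ratio to the mother. GQ03224_L02 passed both limits as a gain instead among the 65 quietest arrays, in tree 618 (1.01 log2). GQ03118_G05 followed among gains (2.76 log2 in tree 700, an array with a noise of 0.680) and GQ03511_E04 among losses (-3.71 log2 in tree 658, with a noise of 0.456). By size alone GQ03112_E06 was past 0.5 log2 on that side in 4 trees, GQ03118_G05 in 4, GQ03224_L02 in 11 and GQ03511_E04 in 10. Of the 6 other genes taken by the rule, each passed both limits in 1 of the 11 noisiest arrays.

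There were 5109 such deviations in 3893 genes, 2570 gains and 2539 losses (exact binomial p = 0.675, and 2539 gains and 2570 losses with the sign turned). In 4230 of the 5109 more than 3 trees were past the size limit alone, so most were not rare by size, and 1335 were in segregating genes. Of their 8900 gene and tree pairs, 43.7% came from the 11 noisiest arrays and 11.3% from the 5 arrays in which neither dye followed the shared profile. In the 65 quietest arrays 1165 deviations were left, 491 gains and 674 losses (exact binomial p = 9.2e-08, and 674 gains and 491 losses with the sign turned). More than 3 trees were past the size limit alone in 199 of the 1165, and 123 were in genes that segregate in those arrays. With 1 tree only there were 1293 losses against 1116 gains (exact binomial p = 0.000334, and 1116 losses against 1293 gains with the sign turned).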

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

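Settings that leave out the 5 arrays, limit array noise, use the labelled dyes, a turned sign, background band, slot or orientation, or remove dye bias were chosen only after the results were seen, as was leaving out the 11 noisiest arrays for transmission and for the other parent against descendants. Of 79 counts under alternatives, 51 stayed within 1.5 times of the value reported.

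Of 689 class distances of named genes under alternatives, 463 kept their call and 226 lost it, and of 26 differences of the other parent 19 kept and 7 lost it. Counts of segregating genes stayed at 1287 to 1763 except at 4 SDs (692), in 2 sets of 57 trees each (512 and 757, 94 genes in both against 68.9 by chance), by correlation of odd and even probes (280), in the 65 quietest arrays (288), in those with the mother in Cy5 (195) and at noise limits of 0.3 (597) and 0.35 (809), while a limit of 0.4 gave 1287 and leaving out the 11 noisiest arrays 1327. Each of these uses fewer trees or another rule by construction, and any further cause was not tested. Genes departing from 1:1 fell from 1670 to 157 in the 65 arrays, where 288 genes were tested. Differences of the other parent from the mother moved from 680 to 1796 at 0.3 log2 and to 90 at 1 log2, by construction.

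Genes in which the other parent departed from the descendants numbered 1 with normexp, 1 with the median over probes, 5 without the dimmest probes, 8 without the 5 arrays, 11 within its background band, 17 without the 11 noisiest arrays and 349 against the 65 quietest, against 2 reported. The cause was not tested. Deviating genes per tree moved from 704 to 1613 at 0.3 log2, 112.5 at 1 log2, 357.5 from the descendants' median and 449 in the 65 arrays. Rare deviations fell from 5109 to 2409 in 1 tree only and 1165 in the 65 arrays. Linked pairs fell from 1348238 to 872518 with 2 principal components removed (870646 by chance), 2732 in the 65 arrays (1491 by chance), 120 there and 1 in all trees without genes departing from 1:1.

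No paired analysis of the 2 groups was possible, since the other parent has only 1 array. Slide or scan as a block, and gene list enrichment with its 2 alternatives, were not run, since slides, scans and gene descriptions are not given in the sources used here. Median Cy5 signal over background was 0.209 in the band of 32 arrays that holds 10 of the 11 noisiest arrays, as ranked over probes. It is not the only limit on precision, since trees 80 and 163 had a ratio of 15.0 and 10.7 with a noise of 0.531 and 0.617. On these 2 arrays Cy5 carried the shared profile. Their median Cy3 signal over background was 2.45 and 0.731.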

Other observations

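In this part, the tests of dye orientation, of array noise, of 1:1 transmission of the block, of 1:2:1 classes and of linkage in the quietest arrays were chosen only after the results were seen. So were the Fisher tests, the correlations within orientations and within the 2 parts of the block's upper class, the values without the 5 arrays, the share of genes with none of them and the genes written out.

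In 7 genes the family's values lay outside those of both parents in the 65 quietest arrays. At least 95% of the trees were 0.5 log2 or more to one side of the mother, and the other parent no more than 0.3 log2 to that side. The other parent's value is 1 array without a replicate check, with a noise of 0.268 against under 0.25 on the 65. The 7 were picked from 5629 genes partly by that value, so the pattern is not shown beyond that array. Of the 7 genes, 4 were above both parents. WS0263_H04 had a median of 2.71 log2 over the trees (SD 0.74) against -0.32 log2 in the other parent, and GQ04003_L21 1.83 log2 (SD 0.50) against -0.19 log2. Below both parents were 3 genes, among them GQ03402_E07 at -1.36 log2 (SD 0.31) against 0.15 log2 in the other parent and GQ03312_J15 at -0.86 log2 (SD 0.19) against -0.23 log2. With the sign turned, the 4 lie below and the 3 above. GQ04006_O12 is of a related kind: 32 of the 65 trees lay at 2.10 log2 and both parents near 0 (0.061 log2 in the other parent). Its upper class held 21 of 40 arrays with the mother in Cy5 and 11 of 25 with the mother in Cy3 (Fisher's exact test, two-sided p = 0.612, adjusted p = 0.839 over 288 genes).

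A block of 24 genes, GQ03610_N24 included, had the same trees in the upper class as that gene, with at most 5% of the 65 quietest trees differing. In 17 of the 24, GQ03610_N24 itself counted, no tree differed. Class distances ran from 0.42 to 4.08 log2 (median 1.52), the lower class lay within 0.3 log2 of the mother in 23 genes, and the other parent was nearer to the upper class in 23. The next largest distances were those of GQ03101_N16 (3.43 log2) and GQ04108_J17 (2.91 log2), whose values in the other parent were 2.52 and 2.46 log2. Among the 49 trees with the upper class, the block's mean over genes split into 38 lower and 11 higher trees, 0.50 log2 apart (0.81 log2 for GQ03610_N24). Together with the 16 trees without it, that makes 16, 38 and 11 trees, which did not differ detectably from 1:2:1 (exact multinomial p = 0.277).

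Ratios of opposite sign on 42 arrays were weighed first. If copy numbers of these trees were truly opposite, the sample dye, Cy5 by the labels, would vary most between arrays, but over 59 genes the SD of Cy3 between them was 3.93 times that of Cy5. That value argues against opposite copy numbers and is what an exchange of the dyes against the labels would give, so exchanged dyes are the likely account. All 42 arrays lie in the lowest Cy5 background band, so whether another difference of that batch adds to it was not tested.

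Small classes among the genes called in 114 trees were weighed next. Arrays with a reference other than the mother are argued against for most of these genes, since 84.3% of them had none of the 5 arrays in which neither dye followed the shared profile in the smaller class (72.4% by chance, median 0% of its trees, mean 4.82% against 4.39% of all trees). The 11 noisiest arrays, which hold 9.65% of the trees, held a median of 50%. They are argued against as the whole cause, since without them 1327 genes were still called, 677 of them among the 1682. Noise of these arrays may therefore account for part of the small classes, and noise of the other arrays or real variants carried by few trees stay open.

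For the block with GQ03610_N24, a technical batch is argued against, since all 5 Cy5 background bands held trees of both classes, with 59.4% to 87.5% in the upper class (permutation p = 0.425) or 59.4% to 90.9% without the 5 arrays of unknown reference (permutation p = 0.171), although in the 65 quietest arrays the upper class held 26 of 40 trees with the mother in Cy5 and 23 of 25 with it in Cy3 (Fisher's exact test, two-sided p = 0.0177, adjusted p = 0.0866). A single heterozygous place passed on evenly is argued against by 77 of 114 trees in the upper class (67.5%, exact 95% interval 58.1% to 76.01%, exact binomial p = 0.000227 against 1:1), and by 70.6% (61.2% to 78.98%, p = 1.9e-05) without the 5 arrays, which are all in the lower class, unless transmission is uneven. DNA of another organism present in varying amount would make the block's genes move together among carriers, and their median pairwise r was 0.536 over 49 trees (0.658 and 0.445 within the 2 orientations), against 0.006 in trees without the block and 0.059 between 31 unlinked genes. The same correlation could come from 1 or 2 doses from 2 separate places. The block's mean was bimodal among carriers (mixture p = 0.00015). Its distance of 0.50 log2 fell just under the bound of 0.5 written beforehand (0.498). Within the 38 lower and 11 higher trees the median pairwise r was 0.264 and 0.270. These parts were split on that same mean, which lowers r under either account. With both places the other parent would hold 2 doses. It lay below the upper class mean in each gene of the block (3.32 against 4.15 log2 for GQ03610_N24). That is 1 array without a replicate check, so doses and foreign DNA cannot be told apart here. A hypothesis left open is thus a block that the other parent and part of the offspring (49 of the 65 quietest trees) carry and the mother lacks, of spruce or of foreign origin. With the sign turned, the mother would carry it, and the other parent and those 49 trees would lack it. Neither origin was tested.

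The hypothesis that trees inherit neighbouring genes together could be tested only through shared classes, since no gene positions are given. The test used the 131 genes whose classes did not depart detectably from 1:1 in the 65 quietest arrays. They gave 120 linked pairs, against at most 1 in 100 permutations of trees within each gene, so chance can be excluded as the source of that number. The permutations also break array effects shared between genes, so this test cannot tell linkage from such effects. Classes of 11 of the 131 genes went with dye orientation (Fisher's exact test, adjusted over 288).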
